A study of Mus musculus with 8 samples.

How the data were processed

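Total RNA was extracted with a column kit from flow-sorted cells of mouse small intestinal epithelium, and libraries were made with the TruSeq RNA kit, per the labels' protocols. Each of the 8 libraries had a gene-level table with 37620 Ensembl genes. Reads were aligned with Bowtie 0.12.8 to the mouse build NCBIM37, per the submitters' processing notes. The names of the tables and their columns are those of MMSEQ, which shares out reads that fit several transcripts or genes. Its version, the annotation release, the strand setting and any filter are not given in the sources used here, so antisense and overlapping genes cannot be told apart by strand, and close paralogs are uncertain. Positions are not printed, since the reference at hand was of a later build and was used for gene names alone. A name was found for 32897 of the 37620 gene IDs (87.4%), which held 99.3% of the counts.

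The deposited tables gave, for each gene, a count of fragments that hit that gene alone, as whole numbers without normalisation. The authors also deposited a log expression estimate that includes shared reads, and the effective length of each gene in that library. No label states the scale of the estimate. The deposited values were read as the natural log of fragments per kilobase of effective length, normalised to library size in mapped fragments, because this reading gives back the unique counts. Every value on estimated counts rests on this reading, and tests on the deposited estimates rest on its log scale. The number of mapped fragments stood in the file headers and ran from 12401668 to 20445879 per library, and between 89.1% and 92.6% of these were unique to 1 gene. Gene-unique counts were the main measurement. For genes with at least 100 reads, estimated counts (the estimate multiplied by effective length and mapped fragments) were 1.31 times the unique count at percentile 95, and their agreement at the median follows from the chosen unit. The log base does not follow from the unit: the slope of the natural log of unique counts, per length and mapped fragments, on the estimate was 0.965 to 0.981 over the 8 libraries, against 0.693 expected for a base of 2. This check was added after the data were seen. Counting unique reads alone lowers the level of genes with near-identical copies, and 187 genes had estimated reads but no gene-unique read.

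The groups were taken from the sample labels. The titles carry numbers 1 to 8, odd in CD24Mid and even in CD24Neg, so no number is shared. Counts were tested with edgeR 4.0.16 in R 4.3.3 (robust quasi-likelihood F test, TMM normalisation, filterByExpr, a model with the group alone), with Benjamini-Hochberg adjustment over 12840 genes and a threshold of 0.05. Fold changes are CD24Mid over CD24Neg, where positive values are higher in CD24Mid. The standard error of a log2 fold change is its size divided by the root of the F statistic. CPM values are normalised with the TMM factors, which ran from 1.34 to 1.42 in CD24Mid and from 0.697 to 0.757 in CD24Neg. On simulated counts for this comparison, with 200 genes changed, the test called 16% of 50 genes changed 1.5-fold, 74% of 50 changed 2-fold, 100% of 50 at each of 4-fold and 8-fold, and 0.0237% of 12655 unchanged genes. The data had far more genes called, and a shift in composition that the simulation left out. These shares therefore do not carry over to the data. Pairs of libraries within a group differed by a chi-square of at least 11.6 per degree of freedom, more than sampling noise, so none was counted as a repeat of another. Ratios of low counts carry 95% exact intervals from SciPy 1.17.1, which cover counting error only, and PCR copies were not removed with molecular identifiers in the sources used here.

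Before the data were examined, 18 gene lists and 14 lists of cell type and region markers were fixed, with 516 places in all, of which 512 matched a gene ID. Each list was counted over all genes tested and adjusted over the list alone. The counts differed between these adjustments for polycomb, tuft and myeloid genes only. Lists with 2 or more measured genes (30 of 32) were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 3, with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the 30 lists. With an estimated correlation none of the 16 lists called was called. fry, which tests whether a list moves one way without comparing it to other genes, called 24. Of 500 random lists of 20 genes, 3.2% had a camera p under 0.05. Random lists are not chosen for related genes, so this rate does not cover lists of correlated genes. Estimated correlations of the fixed lists ran from -0.032 (tuft) to 0.965 (T and NK lymphocyte).

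Genes are named by a rule fixed before the data were examined: 4 genes of the sort (Cd24a, Ptprc, Fut2, Epcam); the 12 genes with the largest change in each direction among those called with a mean log2 CPM of at least 4 and no overlap between groups, passing over predicted genes; up to 2 genes per direction of each list, or its most abundant gene where none was called; and measured genes of the Dnmt, Tet, Uhrf, Tdg and Hells families. This gave 108 genes, of which 106 were carried through the alternatives and the others are not reported here. Library measures were compared by exact permutation over the 70 assignments of 8 libraries to the groups.

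The alternatives fixed beforehand were RLE and upper-quartile factors, no filter on low counts, a filter of 10 CPM in 4 libraries, DESeq2 1.42.0, limma voom with quality weights, limma on the deposited estimates, edgeR on estimated counts, glmTreat against 1.5-fold, and leaving out each library. Another 3 were added after seeing the data: unscaled total counts, removal of mitochondrial genes together with Lars2, and consecutive sample numbers as a block. Figures were drawn with Matplotlib 3.10.9 in Python 3.11.15.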

Results

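Gene expression was profiled by RNA sequencing in 8 libraries of mouse small intestinal epithelium. Cells were sorted by flow cytometry on CD24, a surface glycoprotein that is high on cells at the crypt base and lost on villus cells, after removal of cells positive for CD45, a leukocyte antigen, or for the lectin Ulex europaeus agglutinin I, which binds fucosylated glycans of secretory cells. Of these libraries, 4 came from cells with intermediate CD24 (CD24Mid, also called CD24low by the submitters; numbers 1, 3, 5 and 7) and 4 from cells without CD24 (CD24Neg; numbers 2, 4, 6 and 8). The submitters described them as biological replicates. Total counts of reads unique to 1 gene ranged from 11340782 in CD24Neg replicate 2 to 18928233 in CD24Neg replicate 6. The 4 CD24Mid libraries held 15473071 to 17537818, and the groups did not differ by an exact two-sided permutation test (p = 0.171, n = 4 each). At these depths a gene with no read in a library was limited to between 0.121 and 0.145 CPM (counts scaled to a common normalised library size) in CD24Mid and between 0.218 and 0.38 CPM in CD24Neg, counting error only.

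The comparison of CD24Mid with CD24Neg asked which genes change as intestinal epithelial cells differentiate, the setting in which the series placed its question on 5-hydroxymethylcytosine. Genes of stem and dividing cells were higher in CD24Mid, and genes of absorptive enterocytes, together with all 12 measured mitochondrially encoded genes, were higher in CD24Neg. The sorting marker Cd24a (ENSMUSG00000047139) stood at 194 ± 43.4 CPM in CD24Mid and 28.6 ± 8.37 CPM in CD24Neg (SD, n = 4 each). It was 6.81-fold higher in CD24Mid (log2 fold change 2.77 ± 0.23 SE, edgeR adjusted p = 1.56e-06), with single CD24Mid libraries at 155, 255, 176 and 190 CPM and single CD24Neg libraries at 24.8, 38.5, 19.2 and 31.7 CPM. Of 12840 genes tested, 4557 were higher in CD24Mid and 4410 in CD24Neg at an edgeR adjusted p under 0.05, and 2620 and 2348 of these by more than 2-fold. CD24Mid and CD24Neg libraries did not overlap in 64.4% of the tested genes, against 2.86% by chance. Changes above 16-fold were found for 83 genes higher in CD24Mid and 238 genes higher in CD24Neg, of which 4 and 89 had a mean log2 CPM of at least 4. The first principal component held 85.3% of the variance of log2 CPM and separated the groups. Pearson correlations across genes were 0.970 to 0.989 within groups and 0.793 to 0.855 between them, across genes that are not independent replicates. The direction of small changes depended on scaling. Of the genes called, 50.8% were higher in CD24Mid with TMM normalisation, 61.4% with upper-quartile normalisation and 84.4% on unscaled totals, where the median log2 fold change of all genes moved from 0.015 to 0.24 and 0.96, respectively.

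**Figure D1:**
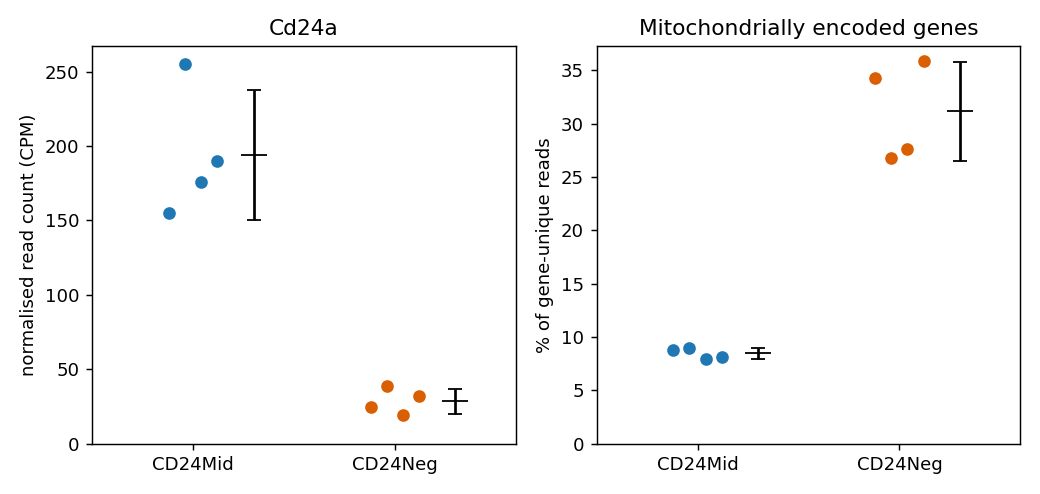
Normalised read count of Cd24a in CPM (left) and percent of gene-unique reads in mitochondrially encoded genes (right) in the 4 CD24Mid and 4 CD24Neg libraries; points are single libraries, and the bars beside them give the mean and SD. CD24Mid libraries lie above all CD24Neg libraries for Cd24a (194 against 28.6 CPM on average) and below them for mitochondrial reads (8.46% against 31.1%).

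The crypt programme was higher in CD24Mid throughout. All 22 stem cell genes, all 29 cell cycle genes and all 20 ribosome biogenesis genes were higher there, with median log2 fold changes of 2.93, 2.96 and 2.25. Lgr5, a marker of crypt base stem cells, was 15.3-fold higher (47.3 ± 9.09 against 3.15 ± 1.58 CPM), and the stem cell factors Ascl2 and Msi1 were 27.5-fold and 26.3-fold higher. Olfm4, a secreted glycoprotein of crypt base cells, reached 3269 ± 428 CPM in CD24Mid against 178 ± 111 CPM in CD24Neg. Smoc2, Cd44, the ion transporter Slc12a2, the actin-binding gene Cnn3 and the fatty acid desaturase Fads1 were 12.6-fold to 14.3-fold higher. Dividing-cell genes rose to a like extent, with the replication helicase subunit Mcm3 13.3-fold, E2f1 13.2-fold, the DNA polymerase subunit Pole 12.9-fold and the condensin subunit Ncaph 12.8-fold higher. Nop56 and Gnl3, nucleolar proteins of ribosome assembly, were 6.68-fold and 6.62-fold higher. Each named gene passed with an edgeR adjusted p of 9.33e-06 or less. As sets, the lists passed camera with a preset correlation (adjusted p = 3.04e-09 for stem cell, 3.03e-12 for cell cycle and 2.40e-09 for ribosome biogenesis), but none passed with an estimated correlation (adjusted p = 0.31 for each). The stem cell list shared 7 of its genes with other lists. The same CD24Mid libraries held more plasma cell transcripts (Igkc 401 against 20 CPM) and enteroendocrine transcripts (19 of 23 genes higher).

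Wnt and Notch genes moved in a more mixed way. Of 20 measured Wnt pathway genes and targets, 15 were higher in CD24Mid, 3 were higher in CD24Neg and 2 did not pass (camera adjusted p = 0.0016; adjusted p = 0.31 with an estimated correlation). Those higher in CD24Neg were Tcf7l2, a transcription factor of the pathway, Sp5, a Wnt target at 20.6 ± 3.76 against 7.82 ± 0.947 CPM, and Notum, a secreted Wnt inhibitor with 65 reads in CD24Neg and 4 in CD24Mid (ratio 37.5, 95% counting interval 14.0 to 142). Tcf7l2 was named because the count was small, after its value was seen. The Wnt counts were 15 and 3 with upper-quartile scaling, and 17 and 2 on unscaled totals. There Sp5 and Notum kept their calls, and that of Tcf7l2 toward CD24Neg was lost. Of 12 measured Notch pathway genes, 6 were higher in CD24Mid and 0 in CD24Neg by edgeR, or 8 and 0 with upper-quartile scaling and 12 and 0 on unscaled totals. The receptors Notch1 and Notch2 were 6.09-fold and 4.99-fold higher (edgeR adjusted p = 5.33e-07 and 9.74e-07). The Notch list just passed camera (adjusted p = 0.043; adjusted p = 0.31 with an estimated correlation). It did not pass without CD24Neg replicate 6 (adjusted p = 0.068) or CD24Neg replicate 8 (adjusted p = 0.056), nor on unscaled totals (adjusted p = 0.053) or on the deposited expression estimates (adjusted p = 0.055).

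Enterocyte genes were higher in CD24Neg by large factors. All 25 brush border digestion and transport genes, all 20 lipid absorption genes and all 22 drug and xenobiotic metabolism genes were higher in CD24Neg, with median log2 fold changes of -3.79, -3.59 and -3.76. With upper-quartile scaling 19 of the 20 lipid genes passed, and on unscaled totals 18. Apoa1 and Apoa4, apolipoproteins of chylomicrons, stood at 10676 ± 2979 and 5871 ± 2410 CPM in CD24Neg against 98.4 ± 27 and 58.6 ± 17.5 CPM in CD24Mid. Lactase (Lct) was 108-fold higher in CD24Neg (2674 ± 1008 against 24.8 ± 5.64 CPM), and the peptide transporter Slc15a1 was 77.9-fold higher. Cubn, an endocytic receptor, was 165-fold higher, with Pdzk1, a scaffold of apical transporters, at 153-fold, Ggt1 at 127-fold and Apoc2 at 115-fold. The phospholipase Plb1 and Nlrp9b, an innate immune sensor, were 101-fold and 103-fold higher. Among drug-metabolising enzymes, Cyp2b10 was 159-fold and Cyp3a11 130.2-fold higher in CD24Neg. Each of these genes passed with an edgeR adjusted p between 9.35e-08 and 1.00e-05. Cyp1a1 was also higher (44.6 ± 71.1 against 0.306 ± 0.342 CPM, edgeR adjusted p = 0.0013), with the size resting on single libraries: its log2 fold change of -7.13 was -4.81 without CD24Neg replicate 6 and -8.18 without CD24Mid replicate 5, and that of Cyp3a11 moved from -7.02 to -6.34 without CD24Neg replicate 4.

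Nucleoside-handling genes of the villus tip followed the enterocyte lists. Of 8 measured, 7 were higher in CD24Neg, among them the nucleoside transporter Slc28a1 (97.1-fold) and the ectonucleotidase Enpp3 (33.9-fold), and Slc29a3, a lysosomal nucleoside transporter, was higher in CD24Mid (16.1 ± 0.755 against 11.5 ± 0.898 CPM, edgeR adjusted p = 0.0025). The antimicrobial and MHC class II list had 10 of 15 measured genes higher in CD24Neg and 0 in CD24Mid by edgeR, or 8 and 0 with upper-quartile scaling and 5 and 1 on unscaled totals. In its MHC class II part, H2-Ab1 and H2-Aa were higher in CD24Neg (edgeR adjusted p = 0.019 and 0.037). H2-DMa, Cd74 and Ciita did not pass (edgeR adjusted p = 0.077, 0.071 and 0.098). Genes of this part were named after their values were seen. Reg3b, a C-type lectin with antibacterial activity, stood at 3047 ± 1384 CPM in CD24Neg and 183 ± 111 CPM in CD24Mid (edgeR adjusted p = 6.70e-05), and Saa1 had 174 reads against 2 (ratio 201, 95% counting interval 54.8 to 1672). With a preset correlation these 5 lists passed camera, with an adjusted p of 3.03e-12 for brush border, 1.24e-09 for lipid absorption, 5.69e-10 for xenobiotic metabolism, 0.0021 for purine metabolism and 0.0045 for antimicrobial genes. None passed with an estimated correlation (adjusted p = 0.31 for the first 4 and 0.46 for antimicrobial genes). The same CD24Neg libraries held more mitochondrial reads (31.1% against 8.46%) and more of the T cell gene Gzma (129.97 against 2.20 CPM).

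**Figure D2:**
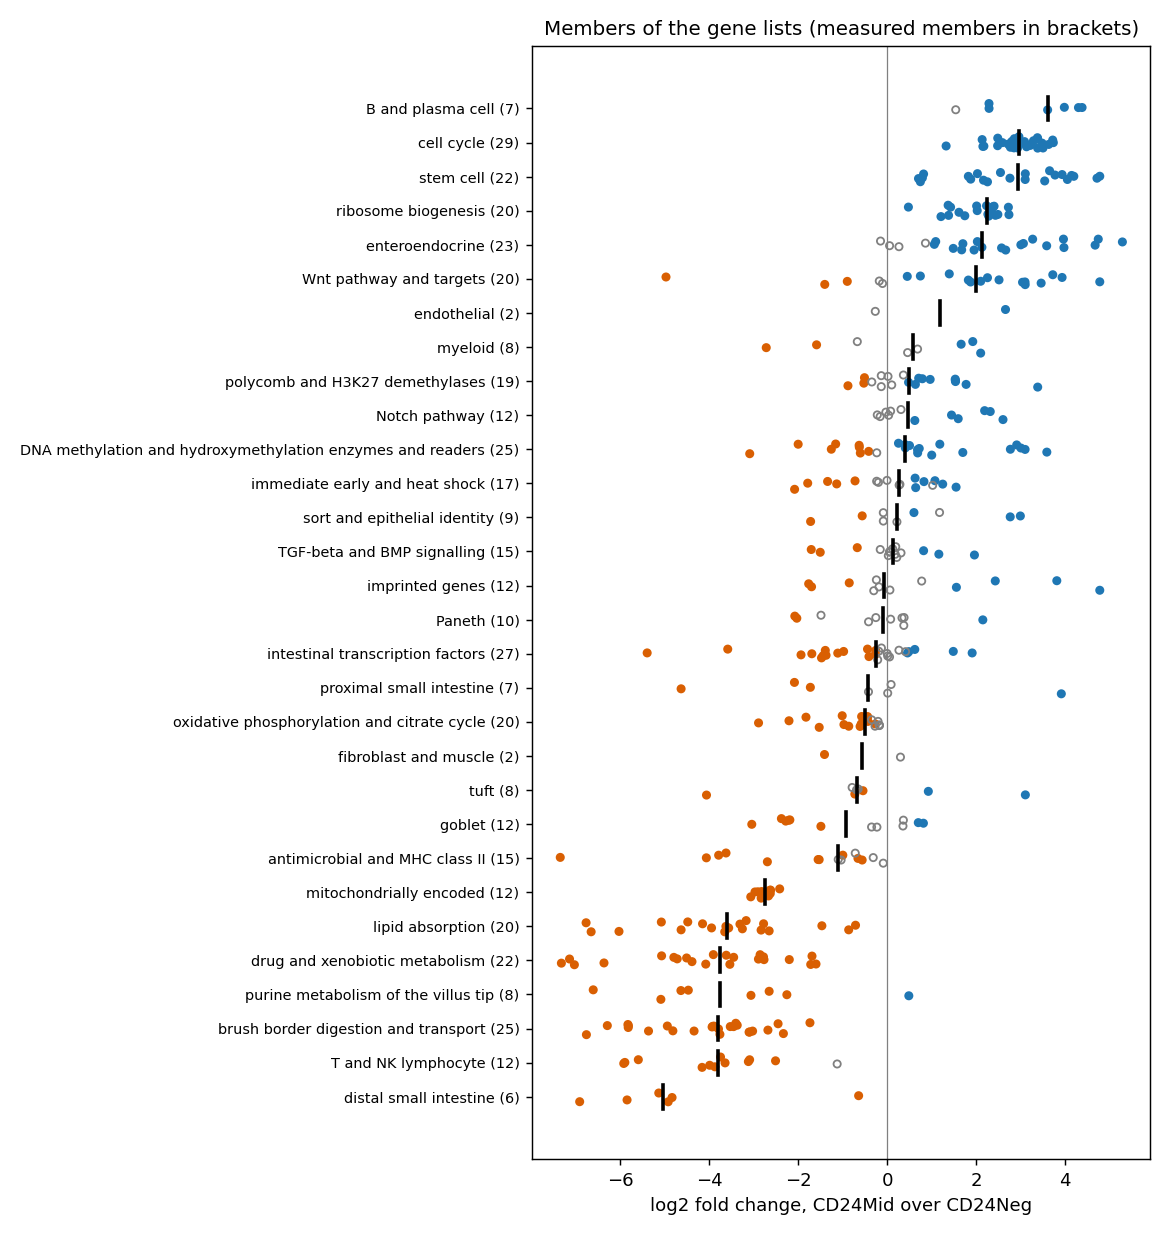
Fitted log2 fold change (CD24Mid over CD24Neg, horizontal axis) of each measured member of the 30 lists with 2 or more measured members, ordered by the list median (black bar); filled points passed the edgeR test at an adjusted p under 0.05 (blue higher in CD24Mid, orange higher in CD24Neg) and open points did not. Cell cycle and stem cell medians lie at 2.96 and 2.93, and brush border and lipid absorption medians at -3.79 and -3.59, whereas on unscaled totals the medians of the respiratory, transcription factor, imprinted, goblet, Paneth, tuft, fibroblast and proximal lists turn above 0.

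Enzymes that maintain, write and oxidise DNA methylation did not move together. Of 25 measured genes for DNA methylation and hydroxymethylation enzymes and readers, 16 were higher in CD24Mid and 8 in CD24Neg, or 16 and 4 with upper-quartile scaling and 18 and 3 on unscaled totals (camera adjusted p = 0.17). The maintenance machinery was higher in CD24Mid: Dnmt1, the maintenance methyltransferase, at 209 ± 20 against 27.8 ± 8.92 CPM (7.54-fold), its partner Uhrf1 at 139 ± 13.2 against 11.7 ± 5.60 CPM (12-fold), and the chromatin remodeller Hells at 67.3 ± 17.5 against 8.30 ± 2.13 CPM (8.05-fold), each with an edgeR adjusted p of 1.52e-06 or less. Their log2 fold changes of 2.91, 3.59 and 3.01 lay within the range of the cell cycle list (1.33 to 3.74, median 2.96). A change in methylation machinery therefore cannot be told apart here from the higher dividing-cell genes of CD24Mid. Of the de novo methyltransferases, Dnmt3b was 3.26-fold higher in CD24Mid but low in both groups (6.63 ± 0.427 and 2.07 ± 0.724 CPM, edgeR adjusted p = 9.84e-05). Dnmt3a differed by 1.20-fold (61.7 ± 5.24 and 51.6 ± 1.58 CPM, edgeR adjusted p = 0.029). This call was lost without CD24Mid replicate 5 (adjusted p = 0.089) or CD24Mid replicate 7 (adjusted p = 0.055) and on estimated counts that include shared reads (adjusted p = 0.24).

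The 3 Tet dioxygenases, which oxidise 5-methylcytosine to 5-hydroxymethylcytosine, had different patterns. Tet1 (ENSMUSG00000047146) was 8.59-fold higher in CD24Mid but the lowest of the family, at 3.09 ± 1.16 against 0.347 ± 0.174 CPM (log2 fold change 3.10 ± 0.42 SE, edgeR adjusted p = 6.64e-05). The CD24Neg mean lay among the limits for a gene with no read there (0.218 to 0.38 CPM), so the size of the Tet1 change is uncertain. This change also lay within the range of the cell cycle list (1.33 to 3.74) and cannot be told apart from the higher dividing-cell genes of CD24Mid. Tet2 (ENSMUSG00000040943) was 1.54-fold higher in CD24Neg, at 36.1 ± 5.99 against 23.4 ± 5.46 CPM (log2 fold change -0.63 ± 0.18 SE, edgeR adjusted p = 0.0096). Tet3 (ENSMUSG00000034832), the most abundant of the family, stood at 105 ± 10.3 CPM in CD24Mid and 123 ± 8.69 CPM in CD24Neg and did not pass (log2 fold change -0.23 ± 0.11 SE, edgeR adjusted p = 0.071). The glycosylase Tdg, which excises oxidised forms of 5-methylcytosine, and Uhrf2 were 1.32-fold and 1.61-fold higher in CD24Mid (edgeR adjusted p = 0.0025 and 0.00036). Idh1, which makes the Tet cofactor 2-oxoglutarate, was 3.99-fold higher in CD24Neg (331 ± 54.4 against 83.0 ± 14.0 CPM), and the cytidine deaminase Apobec1 was 8.48-fold higher there (edgeR adjusted p = 1.29e-06 and 5.86e-07). Idh2, which makes the same cofactor and was named after its value was seen, was 2.01-fold higher in CD24Mid (119 ± 18.2 against 59.2 ± 13.4 CPM, edgeR adjusted p = 0.00034). The Tet2 call was lost without CD24Neg replicate 6 (adjusted p = 0.062) or CD24Neg replicate 8 (adjusted p = 0.065) and with upper-quartile scaling (log2 fold change -0.40, adjusted p = 0.064). On unscaled totals the log2 fold changes of Tet2 and Tet3 turned to 0.32 and 0.72, and with consecutive sample numbers as a block, a fit added after the data were seen, Tet3 passed in the original direction (adjusted p = 0.038).

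**Figure D3:**
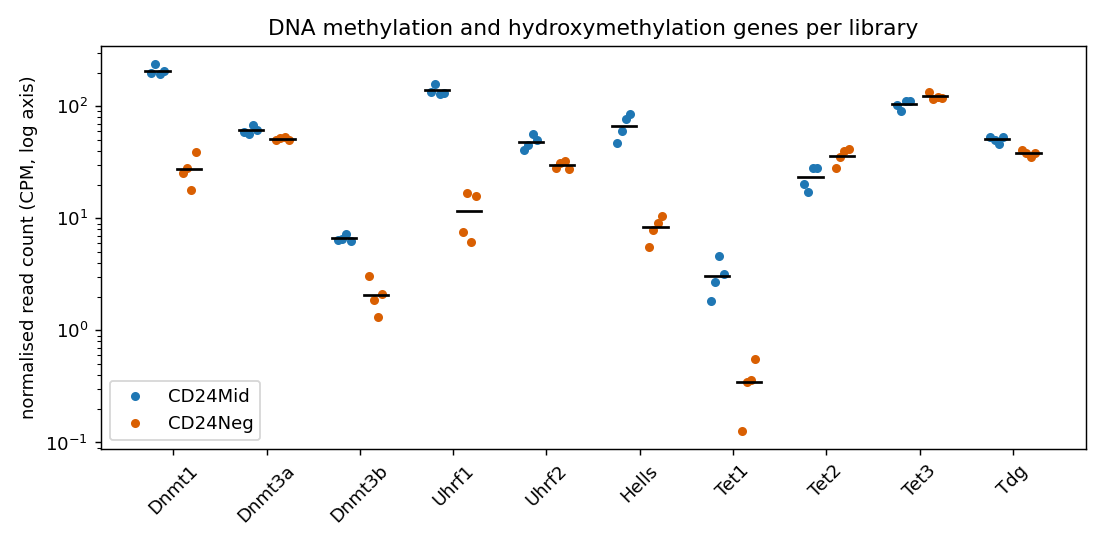
Normalised read count (CPM, log axis) of 10 genes of DNA methylation and hydroxymethylation in each CD24Mid (blue) and CD24Neg (orange) library, with the group mean as a black line. Dnmt1, Uhrf1, Hells, Tet1 and Dnmt3b lie higher in every CD24Mid library, as do Dnmt3a, Uhrf2 and Tdg by smaller factors. Tet3 lies higher in every CD24Neg library. Dnmt3a and Tet3 differ by only 1.20-fold and 1.17-fold, and Tet2 and Tet3 turn direction on unscaled totals.

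Of 19 measured genes of the polycomb and H3K27 demethylases list, 10 were higher in CD24Mid and 3 in CD24Neg, or 10 and 4 adjusted over the list alone (camera adjusted p = 0.10), and these counts were 12 and 2 with upper-quartile scaling and 18 and 0 on unscaled totals. The polycomb-associated factors Phf19 and Rbbp7 were 10.5-fold and 3.43-fold higher in CD24Mid (edgeR adjusted p = 4.08e-05 and 3.42e-07). The H3K27 demethylase Kdm6b was 1.84-fold higher in CD24Neg (120.1 ± 10.3 against 65.4 ± 6.68 CPM, edgeR adjusted p = 3.35e-05), and turned direction on unscaled totals (log2 fold change 0.067).

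Of 27 intestinal transcription factors, 14 were higher in CD24Neg and 5 in CD24Mid, or 7 and 17 on unscaled totals (camera adjusted p = 0.097; median log2 fold change -0.25, or 0.69 on unscaled totals). Maf, a leucine zipper factor, was 11.9-fold higher in CD24Neg (389 ± 45.3 against 32.6 ± 11.2 CPM). The pioneer factors Foxa2 and Foxa1 were 3.77-fold and 2.81-fold higher in CD24Mid. These 3 genes passed with an edgeR adjusted p of 7.02e-05 or less. Of 12 measured imprinted genes, 4 were higher in CD24Mid and 3 in CD24Neg, or 8 and 1 on unscaled totals (camera adjusted p = 0.67), and the median log2 fold change of -0.058 was opposite in sign to the mean (0.70) and to the direction of camera, and turned to 0.17 with upper-quartile scaling and 0.88 on unscaled totals. Ascl2 and the amino acid transporter Slc38a4 led toward CD24Mid, Slc38a4 with 207 reads against 6 (log2 fold change 3.82, or 5.90 without CD24Neg replicate 4). Igf2 and Zrsr1 were 3.39-fold and 3.24-fold higher in CD24Neg (edgeR adjusted p = 0.0018 and 6.11e-06). The Igf2 call was lost on unscaled totals (log2 fold change -0.84 against -1.76, adjusted p = 0.070).

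TGF-beta and BMP signalling genes and stress genes did not pass as sets (camera adjusted p = 0.88 and 0.91). Of 15 measured TGF-beta and BMP genes, 3 were higher in each group, against 8 in CD24Mid and 3 in CD24Neg with upper-quartile scaling and 12 and 2 on unscaled totals. Among them, the BMP ligand Bmp2 and the inhibitor Smad7 were 3.25-fold and 2.83-fold higher in CD24Neg, and the pseudoreceptor Bambi and the receptor Tgfbr2 were 3.90-fold and 2.24-fold higher in CD24Mid. Of 17 immediate early and heat shock genes, 6 were higher in CD24Mid and 5 in CD24Neg, or 12 and 3 on unscaled totals. The chaperones Hsph1 (2.93-fold) and Hspa1b, whose reads are hard to tell from those of its near-identical neighbour Hspa1a (199 ± 70 against 83.9 ± 61.3 CPM, 2.38-fold) were higher in CD24Mid, and the stress factor Ddit3 and the cytokine signalling inhibitor Socs3 were 4.22-fold and 3.44-fold higher in CD24Neg. All passed with an edgeR adjusted p of 0.0019 or less except Hspa1b (edgeR adjusted p = 0.023), which was lost without CD24Neg replicate 2 (adjusted p = 0.059), CD24Neg replicate 4 (0.052) or CD24Mid replicate 7 (0.079) and rose to a log2 fold change of 1.93 without CD24Neg replicate 8. For both lists fry gave the opposite direction to the median.

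Mitochondrially encoded transcripts took 31.1% ± 4.62 of gene-unique reads in CD24Neg and 8.46% ± 0.511 in CD24Mid (SD, n = 4 each; exact two-sided permutation p = 0.0286, the smallest that 70 assignments allow, Benjamini-Hochberg adjusted p = 0.0429 over 6 library measures). All 12 measured genes were higher in CD24Neg (median log2 fold change -2.74), with mt-Co1, a cytochrome oxidase subunit, at 162139 ± 27658 against 19424 ± 1405 CPM and mt-Nd3 7.82-fold higher. Nuclear-encoded genes of oxidative phosphorylation and the citrate cycle changed less: 14 of 20 were higher in CD24Neg, none in CD24Mid, with a median log2 fold change of -0.50 that turned to 0.43 on unscaled totals, where 4 were higher in CD24Neg and 13 in CD24Mid. Cox7a1 and the coactivator Ppargc1a were 7.39-fold and 4.60-fold higher in CD24Neg (edgeR adjusted p = 1.07e-06 and 1.62e-06). The mitochondrially encoded and nuclear lists passed camera (adjusted p = 1.89e-05 and 0.00057), and neither passed with an estimated correlation (adjusted p = 0.33 and 0.46). On unscaled totals the nuclear list did not pass camera with the preset correlation either (adjusted p = 0.19). The 10 most counted genes held 31.5% ± 4.32 of the reads in CD24Neg and 10.3% ± 0.353 in CD24Mid, and 16271 ± 239 genes had a read in CD24Neg against 18105 ± 186 in CD24Mid (exact permutation p = 0.0286 each). These permutation tests took the libraries as independent. If consecutive numbers were prepared together, fewer assignments are allowed and the smallest possible p is larger.

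Enteroendocrine genes were higher in CD24Mid, with 19 of 23 measured higher there and none in CD24Neg (median log2 fold change 2.13; camera adjusted p = 0.00014; adjusted p = 0.42 with an estimated correlation; adjusted p = 0.054 with the preset one on unscaled totals). Neurog3, the transcription factor that specifies endocrine cells, had 755 reads in CD24Mid and 8 in CD24Neg (edgeR adjusted p = 1.46e-05). The hormone gene Gip was 26.8-fold higher but varied widely (147 ± 177 against 5.61 ± 6.54 CPM, edgeR adjusted p = 0.0015), and its log2 fold change of 4.75 was 3.45 without CD24Mid replicate 3 and 5.95 without CD24Neg replicate 4. That of Neurog3 rose from 5.29 to 6.35 without CD24Neg replicate 4.

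Goblet genes went both ways, with 6 of 12 higher in CD24Neg and 2 in CD24Mid, or 5 and 6 on unscaled totals (camera adjusted p = 0.20; median log2 fold change -0.92, or 0.023 on unscaled totals). The mucin Muc2 was 5.18-fold higher in CD24Neg (2560 ± 1320 against 494 ± 99.2 CPM) and the lectin Zg16 8.22-fold (edgeR adjusted p = 0.00011 and 6.49e-05). Creb3l1, a transcription factor of secretory cells, and the glycosyltransferase Galnt12 were 1.76-fold and 1.63-fold higher in CD24Mid (edgeR adjusted p = 0.0090 and 0.013). Of 10 measured Paneth cell genes, Mmp7, the protease that activates defensins, was 4.45-fold higher in CD24Mid, and the defensins Defa21 and Defa22, close paralogs with uncertain read assignment, were 4.2-fold and 4.07-fold higher in CD24Neg (edgeR adjusted p = 1.43e-05, 0.020 and 0.018). The Paneth list did not pass camera (adjusted p = 0.98), and fry and the median of -0.085 lay in opposite directions. That median turned to 0.14 with upper-quartile scaling and 0.84 on unscaled totals, where 4 genes were higher in CD24Mid and 0 in CD24Neg. Without CD24Neg replicate 4 the defensin calls were lost and their log2 fold changes moved from -2.07 and -2.03 to -0.91 and -0.93 (adjusted p = 0.13 and 0.11). Both were lost on unscaled totals (adjusted p = 0.15 each), and that of Defa21 was lost without CD24Mid replicate 1, 5 or 7 (adjusted p = 0.054, 0.054 and 0.051).

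Tuft cell genes were sparse, with 8 of 18 measured, 2 higher in CD24Mid and 3 in CD24Neg, or 2 and 4 adjusted over the list alone and 2 and 1 with upper-quartile scaling or on unscaled totals (camera adjusted p = 0.48; median log2 fold change -0.67, or 0.27 on unscaled totals). The leukotriene synthase Ltc4s was 16.6-fold higher in CD24Neg and the tuft cell factor Pou2f3 8.62-fold higher in CD24Mid (edgeR adjusted p = 1.12e-05 and 0.0015), the latter with a log2 fold change of 3.11 that was 4.18 without CD24Neg replicate 4. Alox5ap and Il17rb passed narrowly in opposite directions (log2 fold change 0.93 and -0.72, edgeR adjusted p = 0.043 and 0.047). Leaving out single libraries ended the Alox5ap call for CD24Mid replicates 1, 3 and 7 and CD24Neg replicates 6 and 8 (adjusted p = 0.090, 0.074, 0.10, 0.103 and 0.092). The Il17rb call ended without any library other than CD24Mid replicate 1 (adjusted p up to 0.18), it was lost with upper-quartile scaling (adjusted p = 0.15), and its direction turned on unscaled totals (log2 fold change 0.21).

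Lymphocyte markers remained in both groups despite the CD45 depletion and differed in kind. Of 12 measured T and NK lymphocyte genes, 11 were higher in CD24Neg (median log2 fold change -3.8; camera adjusted p = 0.012; adjusted p = 0.62 with an estimated correlation). The granzymes Gzma (129.97 ± 126 against 2.20 ± 1.43 CPM) and Gzmb (45 ± 41.8 against 0.751 ± 0.616 CPM) were 59.3-fold and 60.3-fold higher, with Gzma at 277 and 191 CPM in CD24Neg replicates 2 and 8 and at 14.6 and 37.0 CPM in replicates 4 and 6. Without CD24Neg replicate 2 their log2 fold changes moved from -5.89 to -5.16 and from -5.92 to -5.25, and that of Gzmb was -6.60 without CD24Mid replicate 1. Of 7 measured B and plasma cell genes, 6 were higher in CD24Mid (median log2 fold change 3.61; camera adjusted p = 0.0049; adjusted p = 0.31 with an estimated correlation; adjusted p = 0.14 with the preset one on unscaled totals). The immunoglobulin genes Igkc and Jchain stood at 401 ± 141 and 379 ± 131 CPM in CD24Mid against 20 ± 6.86 and 19.3 ± 6.80 CPM in CD24Neg, and the B cell coactivator Pou2af1 had 450 reads against 9 (edgeR adjusted p = 1.72e-06, 1.36e-06 and 3.58e-06).

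**Figure D4:**
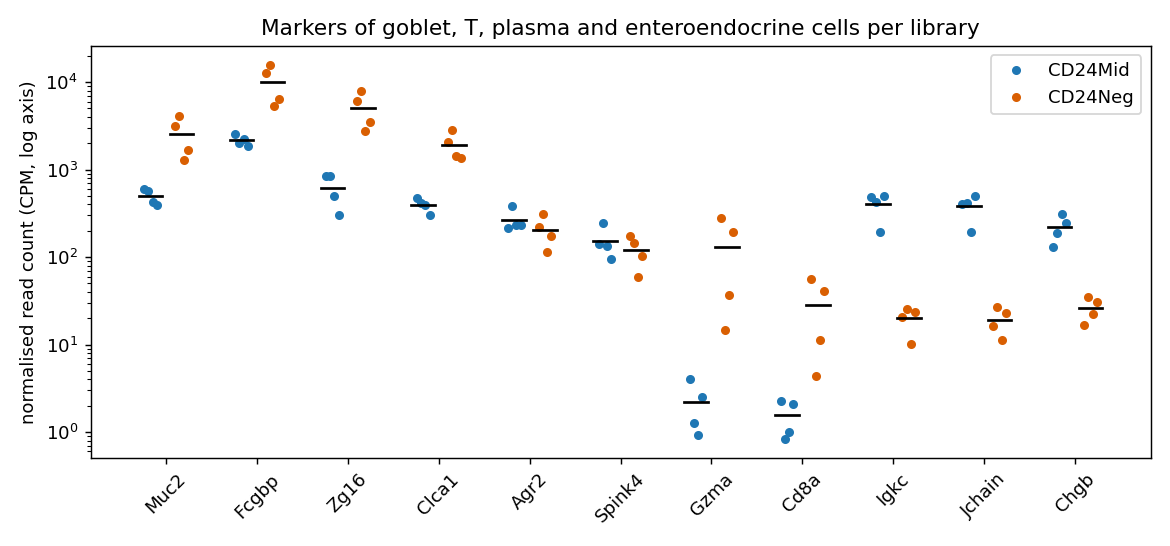
Normalised read count (CPM, log axis) of goblet (Muc2, Fcgbp, Zg16, Clca1, Agr2, Spink4), T cell (Gzma, Cd8a), plasma cell (Igkc, Jchain) and enteroendocrine (Chgb) genes in each CD24Mid (blue) and CD24Neg (orange) library, with the group mean as a black line. Gzma averages 2.20 CPM in CD24Mid and 129.97 CPM in CD24Neg, whereas Igkc averages 401 and 20 CPM.

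Other cell types left little signal. Of 8 measured myeloid genes, 3 were higher in CD24Mid and 2 in CD24Neg, or 2 and 1 adjusted over the list alone and 5 and 1 with upper-quartile scaling or on unscaled totals (camera adjusted p = 0.48). Cd14 and Csf1r were 4.30-fold and 3.8-fold higher in CD24Mid and Fcer1g and Tyrobp 6.56-fold and 3.0-fold higher in CD24Neg (edgeR adjusted p = 0.00015, 0.043, 0.0034 and 0.048). The Csf1r call was lost without CD24Mid replicate 1 or 7 or CD24Neg replicate 2, 4 or 6 (adjusted p = 0.087, 0.136, 0.093, 0.102 and 0.112), and its log2 fold change of 1.93 was 3.15 without CD24Neg replicate 8. That of Tyrobp was lost without any library other than CD24Neg replicates 4 and 6 (adjusted p up to 0.22, without CD24Neg replicate 2, where its log2 fold change moved from -1.58 to -0.89). It was also lost with upper-quartile scaling (adjusted p = 0.080) and on unscaled totals (adjusted p = 0.38). Of the fibroblast and muscle list 2 of 12 genes were measured, with Tagln 2.66-fold higher in CD24Neg (edgeR adjusted p = 0.00026; camera adjusted p = 0.65). The Tagln call was lost on unscaled totals, where its log2 fold change moved from -1.41 to -0.47 (adjusted p = 0.071). Of the endothelial list 2 of 7 genes were measured, with Esam 6.27-fold higher in CD24Mid (edgeR adjusted p = 2.22e-05; camera adjusted p = 0.48). No erythroid gene was measured, and of the pancreatic acinar list the single measured gene Cela1 stood at 2.58 ± 0.857 and 3.51 ± 0.644 CPM and did not pass (edgeR adjusted p = 0.18).

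Markers of gut region also moved, although these lists cannot tell a difference in region from the higher enterocyte genes of CD24Neg. Fabp1, a proximal marker, is also in the lipid absorption list. All 6 distal genes were higher in CD24Neg, or 5 with 1 higher in CD24Mid on unscaled totals (median log2 fold change -5.02; camera adjusted p = 0.0012; adjusted p = 0.31 with an estimated correlation). They were led by the sphingomyelinase Enpp7 (119.9-fold, edgeR adjusted p = 3.57e-07) and the bile acid transporter Slc10a2 (57.3-fold, edgeR adjusted p = 2.16e-06). Of 7 proximal genes, 1 was higher in CD24Mid and 3 in CD24Neg, or 3 and 2 on unscaled totals, where the median log2 fold change turned from -0.42 to 0.52 (camera adjusted p = 0.48). Gkn3 was 15.1-fold higher in CD24Mid, and the fatty acid binding protein Fabp1 (24.7-fold) and the duodenal iron reductase Cybrd1 (4.23-fold) were higher in CD24Neg (edgeR adjusted p = 6.49e-05, 3.07e-06 and 0.0059). The Cybrd1 call was lost on unscaled totals (log2 fold change -1.17, adjusted p = 0.080). Without CD24Neg replicate 4 the log2 fold changes of Gkn3 and Cybrd1 moved from 3.92 to 4.64 and from -2.08 to -1.14.

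Among 9 genes of sort and epithelial identity, 3 were higher in CD24Mid and 2 in CD24Neg, or 5 and 0 with upper-quartile scaling and 8 and 0 on unscaled totals (camera adjusted p = 0.48). The epithelial adhesion gene Epcam stood at 1300.3 ± 124 and 1378 ± 61.9 CPM and did not pass (edgeR adjusted p = 0.57; log2 fold change -0.083, or 0.86 on unscaled totals). Ptprc, which encodes CD45, was 3.29-fold higher in CD24Neg (18 ± 15.8 against 5.42 ± 2.89 CPM, edgeR adjusted p = 0.039), a call that 12 of 19 alternatives lost. These included leaving out CD24Mid replicate 1, 3 or 5 (adjusted p = 0.075, 0.082 and 0.091) or CD24Neg replicate 2 or 8 (adjusted p = 0.104 and 0.200), and without CD24Neg replicate 8 its log2 fold change moved from -1.72 to -0.97. Fut1 and Fut2, fucosyltransferases that make the glycan bound by the depletion lectin, had group means below 1 CPM. Fut1 had 79 reads in CD24Mid and 4 in CD24Neg (edgeR adjusted p = 0.0016; log2 fold change 3.0, or 3.63 without CD24Neg replicate 8), and Fut2 had 55 and 10 and passed only without CD24Neg replicate 4, with upper-quartile scaling or on unscaled totals (edgeR adjusted p = 0.054, and 0.030, 0.026 and 0.0022). Keratin Krt8 was 1.47-fold higher in CD24Neg (edgeR adjusted p = 0.021), a call that was lost without CD24Neg replicate 2 or CD24Mid replicate 3, 5 or 7 (adjusted p = 0.060, 0.051, 0.062 and 0.067). It was also lost with upper-quartile scaling (adjusted p = 0.13) and turned on unscaled totals (log2 fold change 0.38).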

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

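Tests of scaling, of nuclear respiratory genes, of goblet cells of one kind and of splits by consecutive numbers were chosen after the values they measure were seen, and the others before. A library far from the other 3 of its group was found in 8 of 224 sets of 4 values checked, where chance gives about 11.2. The values were 0.878 CPM for Fut2 in CD24Mid replicate 5 (others 0.485 to 0.523), 3.82 CPM for Cubn in CD24Mid replicate 7 (3.26 to 3.30), 104 CPM for Idh1 in CD24Mid replicate 1 (74.0 to 77.6) and 0.0726 CPM for Phf19 in CD24Neg replicate 6 (0.694 to 0.887). The rest were 55.5 CPM for Kdm6b in CD24Mid replicate 3 (67.4 to 69.6), 3.36 CPM for Foxa2 in CD24Neg replicate 4 (1.88 to 2.03), 18.9 CPM for Smad7 in CD24Mid replicate 3 (23.1 to 23.8) and 51.7 CPM for Creb3l1 in CD24Mid replicate 3 (34.8 to 36.5). Outside the main measurement, 187 genes had reads in the deposited estimates but no gene-unique read, 45 of them with an estimated 1000 reads or more over all libraries, and together they held 0.862% of the estimated counts.

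The 3.68-fold higher share of mitochondrially encoded reads in CD24Neg was measured on unscaled counts without overlap between the groups, which argues against TMM scaling as its source. An equal rise of nuclear-encoded respiratory genes was also argued against, since their median log2 fold change of -0.505 lay outside the range of the mitochondrial genes (-3.06 to -2.41). Damaged cells that lost cytoplasmic RNA stay open: the nuclear-retained transcripts Malat1 and Neat1 were higher in CD24Neg too (median log2 fold change -1.81, more than 50% of the mitochondrial median of -2.74), although on unscaled totals the 2 medians were -0.874 and -1.79, just short of that bound. With 2 transcripts measured, the test is thin. A higher mitochondrial content of differentiated cells was not tested and is open as well.

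T cells carried into the CD24Neg sort and plasma cells carried into the CD24Mid sort are candidate sources of the lymphocyte signal, although the depletion of CD45 positive cells should remove both where they carry that antigen. For plasma cells, 6 genes outside the fixed lists had a median log2 fold change of 2.48 toward CD24Mid, as such cells would give. Igkc, at 401 CPM against 20 CPM, is among them but is also part of the signal to be explained, so it adds no separate support. Of the others, Derl3, Irf4 and Tnfrsf13b were higher in CD24Mid (log2 fold change 3.13, 2.81 and 2.14). Ighm and Eaf2 did not pass (log2 fold change 0.55 and 0.16, edgeR adjusted p = 0.31 and 0.56). For T cells, 11 pan-lymphoid genes had a median of -0.890, between the bounds set beforehand (-1 and -0.5), and none passed the edgeR test; Gzma reached 129.97 CPM. Coro1a, like Gzma, was higher in CD24Neg replicates 2 and 8 (21.9 and 16.1 CPM) than in replicates 4 and 6 (1.74 and 3.05 CPM), whereas Cd69 was highest in CD24Mid replicate 7. The median fell between the bounds. Pan-lymphoid genes are not confined to T cells, and plasma cell transcripts were higher in CD24Mid. With these genes T cells and other sources therefore cannot be told apart. Within CD24Neg, Ptprc was at 22.4 and 38.2 CPM in replicates 2 and 8 and at 2.78 and 8.57 CPM in replicates 4 and 6. Cd8a was at 55.5 and 41.0 CPM against 4.40 and 11.2 CPM in the same libraries. Of the fixed T and NK list 6 of 12 measured genes, and of the B and plasma list 1 of 7, reached 1 CPM in both groups, and neither list shared a gene with another.

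Goblet secretory products rose in CD24Neg (Muc2, Fcgbp, Zg16, Tff3 and Clca1, log2 fold changes -3.04 to -2.18) while Agr2, Spink4, Spdef and Ern2 had log2 fold changes of 0.37, 0.36, -0.23 and -0.35 and did not pass. These 2 sets lay 0.771 apart on the log2 scale after 2 standard errors on each side, but they were formed after the values were seen and Bcas1 (-1.49) lay between them, so a higher share of goblet cells of one kind and other sources cannot be told apart. Reads shared with related genes are argued against, since on estimated counts that include them, with the scale of the deposited estimate inferred from its values, the 5 products kept log2 fold changes of -2.17 or lower. Goblet cells that carry the glycan bound by the depletion lectin should have been removed by the sort, and carried-over RNA of abundant secretory transcripts was not tested.

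Of the 35 ways to split the 8 libraries into 4 and 4, 1 split, the labelled one, called 8967 genes, and the highest of the others called 0. The others hold the difference between CD24Mid and CD24Neg within their groups, which lowers their calls, so only the rank of the labelled split is informative. By that rank a chance split can be excluded only if the 8 libraries were independent. If consecutive numbers were prepared together, 8 splits part all 4 pairs, which are too few for a share under 0.05.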

How the results depend on the processing

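Unscaled totals, removal of mitochondrial genes, the matching of consecutive numbers and the block were chosen after the data were seen. No paired analysis was possible from the labels, because the groups share no sample number. As a hint from the data, consecutive numbers deviated together (correlations across genes 0.359 to 0.428, mean 0.395, highest of the other 23 matchings 0.195), and 1 of 24 matchings, the consecutive one, reached that mean (exact p = 0.0417), so consecutive samples may have been prepared together; a block of these numbers, which the labels do not describe as pairs, called 9684 genes against 8967.

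Genes called by both the main test and an alternative kept their direction under each alternative except unscaled totals, where 6216 of 7288 did. Counts of genes higher in CD24Mid and genes higher in CD24Neg moved by over 1.5 times with glmTreat (2860 and 2718, fewer by its construction) and on unscaled totals (8959 and 1659, and 6213 and 1046 by more than 2-fold), and those higher in CD24Neg by more than 2-fold with the 10 CPM filter (1482, fewer genes tested). On unscaled totals 6 reported genes reversed, to log2 fold changes of 0.86 for Epcam, 0.38 for Krt8, 0.21 for Il17rb, 0.067 for Kdm6b, 0.32 for Tet2 and 0.72 for Tet3. Of 102 reported genes called, 82 kept the call under each alternative that tested them. The difference in mitochondrial share of 22.7 percentage points ran from 21.1 to 24.1 when libraries were left out.

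With an estimated correlation no list passed: the adjusted p was 0.31 for stem cell, cell cycle, Wnt, Notch, ribosome biogenesis, brush border, lipid, purine, xenobiotic, B and plasma and distal lists, 0.334 for mitochondrial genes, 0.416 for enteroendocrine, 0.46 for respiratory and antimicrobial and 0.617 for T and NK lists. Notch was 0.0550 on deposited estimates, 0.0529 on unscaled totals and 0.0350 to 0.0679 when libraries were left out. Unscaled totals gave 0.140 for B and plasma, 0.0538 for enteroendocrine, 0.192 for respiratory, 0.0294 for goblet and 0.0489 for polycomb genes. Without a filter, transcription factors and polycomb reached 0.0375 and 0.0400. With fry, which compares a list with no other genes, methylation (3.63e-05), polycomb and transcription factor (5.64e-05 each), imprinted (0.0258), tuft (0.00525), fibroblast (0.00319), endothelial (0.00246) and sort (0.0121) lists passed. Where no construction is named, the cause was not tested. At this depth, number of libraries and simulated dispersion, and with 200 genes changed, 16% of simulated 1.5-fold changes were called. That share does not carry over to the data, where smaller changes such as Tdg at 1.32-fold were called. Which of these settings limits the simulated calls was not tested.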

Other observations

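The families below were formed from gene symbols after the data were seen, 85 families of at least 15 tested genes each. Genes named Rpl or Rps were higher in CD24Mid, 84 of 97 measured against 7 in the other direction (median log2 fold change 1.06; camera adjusted p = 1.18e-07; adjusted p = 0.62 with an estimated correlation). These are the symbols of cytosolic ribosomal proteins, but a symbol alone does not show that each gene is one. Many ribosomal protein genes also have processed copies that share reads. Centromere protein genes (Cenp, 18 of 21, median 2.50), nucleoporins (Nup, 20 of 22, median 1.21), genes named Rad (16 of 18, median 1.31) and centrosomal Cep genes (25 of 35, median 1.18) were higher in CD24Mid too. Zinc finger genes named Zfp moved by less, with 128 of 312 higher in CD24Mid and 36 in CD24Neg (median 0.34), or 170 and 25 with upper-quartile scaling and 273 and 4 on unscaled totals. Medians of these families stayed above 0 under each scaling tried. Apart from the Rpl and Rps family and the Zfp family (adjusted p = 0.62 for both), the adjusted p with an estimated correlation was 0.38 for each, and the camera adjusted p ran from 3.16e-05 for Nup to 0.019 for Zfp.

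Cytochrome P450 genes were higher in CD24Neg, 29 of 38 against 5 (median log2 fold change -3.06; camera adjusted p = 3.16e-05; adjusted p = 0.38 with an estimated correlation). So were glutathione transferases (Gst, 14 of 20 against 2, or 11 against 6 on unscaled totals, median -1.81; adjusted p = 0.0038, or 0.62 with an estimated correlation) and ABC transporters (22 of 31 against 5, or 14 against 11 on unscaled totals, median -1.20 and -0.25; adjusted p = 0.00059, or 0.38 with an estimated correlation). Solute carriers were the largest transporter family, with 138 of 252 higher in CD24Neg and 52 in CD24Mid (median -0.67), and subunits of the vacuolar proton pump followed, with 14 of 16 higher in CD24Neg and 1 in CD24Mid (Atp6v, median -0.75). Both families passed camera (adjusted p = 9.36e-05 and 0.0018) but not with an estimated correlation (adjusted p = 0.38 each), and on unscaled totals their medians turned to 0.27 and 0.19, with 90 solute carriers higher in CD24Neg and 118 in CD24Mid, and 3 and 6 pump subunits.

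Lars2, named after its value was seen, is a nuclear gene for a mitochondrial leucyl-tRNA synthetase and was among the more counted genes. Lars2 stood at 10881 ± 4150 CPM in CD24Neg and 2279 ± 812 CPM in CD24Mid (log2 fold change -2.26 ± 0.35 SE, edgeR adjusted p = 0.00018, n = 4 each). It was among the 10 most counted genes in CD24Neg replicates 2 and 8, where the mitochondrial share was highest (34.3% and 35.9%). Whether all its reads come from the synthetase transcript was not tested.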
